A study of Drosophila melanogaster with 3 samples.

How the data were processed

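The series is a chromatin immunoprecipitation sequencing (ChIP-seq) experiment in S2R+ cells, an established Drosophila melanogaster line derived from embryonic cells. It comprised 2 libraries made with a rabbit antibody against Dp1 and 1 library of input DNA. The name Dp1 has been used for more than one fly protein, the dimerisation partner of the E2F transcription factors and a KH-domain protein that binds dodeca satellite DNA, and the labels do not say which was meant. The labels do not state that the ChIP replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

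Reads were aligned with Bowtie 0.11.3 to the dm3 build, per the submitters' processing notes. The deposited read files list 1 genomic position and strand per aligned read and hold no counts per gene. All reads were 35 bases long, and the read names placed the 3 libraries in 3 lanes of 1 run, with 1 lane for each library. Lane and library can therefore not be separated. The authors also deposited 1 peak list, with a score per peak. Per the file itself the peak names begin with MACS. The caller's version and settings, the meaning of the score and the libraries that entered the call are not given in the sources used here. The peak list may therefore not be independent of the libraries compared with it. Mitochondrial reads carry another sequence name in the ChIP files than in the input file, and both names were joined.

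From these positions, reads were counted per peak and per bin. The fragment length was estimated by strand cross-correlation as 324 bp for Dp1 ChIP replicate 1, 358 bp for replicate 2 and 234 bp for the input, and each 5' end was moved to the centre of such a fragment. Library sizes were the reads in the 8418 bins of 10 kb on the 6 main arms (2L, 2R, 3L, 3R, 4 and X) that overlapped no peak. For each region, log2 of the reads plus 0.5, scaled by the background reads of the library, was compared between ChIP and input with limma 3.58.1 in R 4.3.3 (empirical Bayes moderation with a mean trend, 1 residual degree of freedom). A region was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 fold of at least 1. The single input was assumed to vary like the ChIP libraries. Bins with under 20 reads over the 3 libraries were left out. An exact binomial test of each ChIP library against the input, two-sided, was run beside it. That test treats every read as independent, which amplified copies are not. Each count was also made with 1 read per position and strand, referred to as distinct reads. Both ends of 1 fragment can still be counted on opposite strands. The binomial test on distinct reads then also treats dependent reads as independent. Distinct reads approach their ceiling on short repeated segments, which inflates ChIP folds there because the deeper input reaches that ceiling first. Other computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

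Depth was 2986486 reads for Dp1 ChIP replicate 1, 8424664 for replicate 2 and 12265674 for the input. The distinct positions numbered 890465, 1081983 and 10941249 in the same order. Intervals on shares of reads are exact Clopper-Pearson 95% intervals and cover counting error only, since reads without molecular identifiers are not independent molecules. The limma step was tested on simulated counts with 200 changed regions. For the deposited peaks with all reads it recovered 2% of 2-fold, 20% of 4-fold, 56% of 8-fold and 96% of 16-fold changes, with 5 calls among 4537 unchanged peaks. With distinct reads it recovered 4% of 2-fold, 60% of 4-fold and 100% of 8-fold changes at peaks. For 1-kb bins of the main arms with all reads it recovered 0% of 2-fold, 2% of 8-fold and 12% of 16-fold changes, and with distinct reads 0% of 2-fold, 46% of 4-fold and 98% of 8-fold changes. The shared input was allowed for by simulating unchanged libraries, with rates from the 3 libraries together and the spread between the ChIP libraries, in 20 draws; the simulation was set up after the values were seen. Part of any overlap or correlation between the replicates may come from the shared input.

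The named regions were the 20 peaks with the highest lower value of both replicates' log2 folds and the 3 strongest peaks of each arm by the same value, a rule set before the data were examined. The 5 arm peaks that rank highest by the same value with distinct reads were added after the values were seen, as was the set of arm peaks that passed the binomial test in both libraries with all reads and with distinct reads at under 1.5 input reads per position. The strand measures were also chosen after the values were seen. The strand offset of a peak is the median position of minus-strand 5' ends less that of plus-strand 5' ends, over distinct reads of both ChIP libraries, for peaks with at least 5 ends per strand.

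No genome sequence or gene annotation in the dm3 build was used here, so peaks were not assigned to genes, and the comparisons of peaks with transcription starts, gene lists and sequence motifs were not run. The planned promoter comparison was replaced by 1-kb bins over all sequences. Alternatives tried were other library scalings, distinct reads, a pseudocount of 5, no shift, limma-voom weights, the binomial tests, thinning to the shallowest library, bins of 500 bp, no filter on low bins, and the higher-scoring peaks alone.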

Results

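The data comprised 2 Dp1 ChIP libraries and 1 input DNA library from S2R+ cells, together with a deposited list of 4737 peaks. Dp1 ChIP replicate 1 held 2986486 reads at 890465 distinct positions, or 3.35 reads per position. Replicate 2 held 8424664 reads at 1081983 positions, or 7.79 per position, and the input held 12265674 reads at 10941249 positions, or 1.12 per position. The additional reads of replicate 2 therefore added few positions, and the median peak held 9 distinct reads in replicate 1, 12 in replicate 2 and 58 in the input. Peaks had a median width of 570 bp (330 to 4939), and the authors' score per peak had a median of 74.2. All coordinates are in dm3 and counted from 1. Genes at these positions were not analysed here.

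The first comparison asked where the genome of these cells held more Dp1 ChIP than input reads. Over the deposited peaks the median log2 fold over input was 0.97 in replicate 1 and 1.23 in replicate 2 (mean 1.10, SD 0.18, n = 2). The 4322 peaks on arms 2L, 2R, 3L, 3R and X had medians of 0.95 and 1.21, and the 208 peaks on heterochromatin sequences had 0.92 and 1.36. The 125 peaks on Uextra, a collection of unplaced and largely repetitive scaffolds, stood far higher at 3.89 and 2.47 (mean 3.18, SD 1.0, n = 2). Both replicates lay above the input at 3969 peaks (83.8%), and at 4315 (91.1%) with distinct reads.

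Around the centres of the 4336 peaks on the 6 main arms, ChIP reads formed a narrow summit that the input nearly lacked. Read density within 250 bp of the centre was 2.57 times the flanks in replicate 1 and 2.68 times in replicate 2, against 1.16 times in the input. With distinct reads these ratios were 2.05, 2.17 and 1.14. The libraries that entered the peak call are not given. If these ChIP libraries did, a summit and folds above the input at the peaks follow in part from the choice of peaks. Of all reads, 17.9% (95% interval 17.9 to 18.0) lay in peaks in replicate 1, 11.8% (11.8 to 11.8) in replicate 2 and 4.35% (4.34 to 4.37) in the input. On the main arms alone the shares were 6.34%, 6.88% and 3.22%. These shares were not tested; with 2 libraries against 1 the smallest exact permutation p is 0.333.

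**Figure D1:**
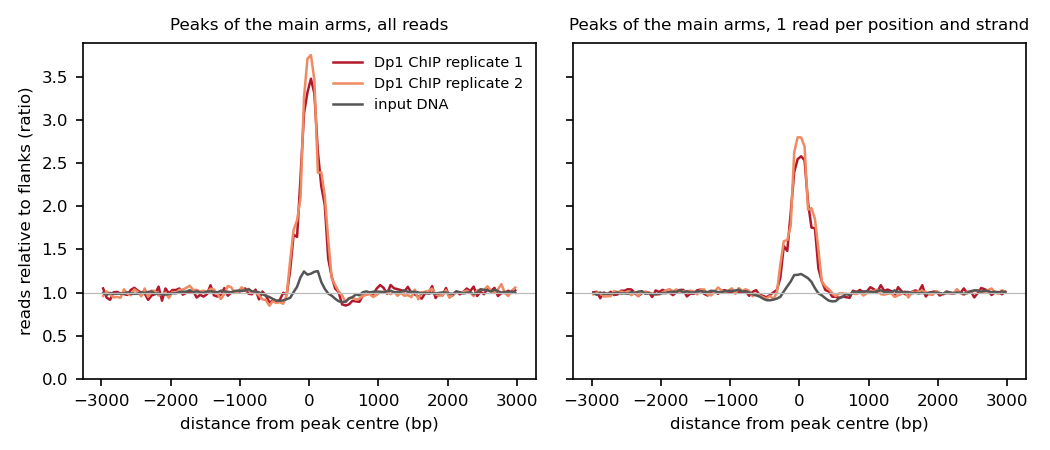
Reads relative to the flanks (vertical axis, ratio to the mean beyond 2 kb) against distance from the peak centre (horizontal axis, bp) over 4336 peaks of the main arms, with all reads on the left and 1 read per position and strand on the right; each line is 1 library. Within 250 bp of the centre the ChIP lines average 2.57 and 2.68 with all reads and 2.05 and 2.17 with distinct reads, and the input line 1.16 and 1.14.

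Peak by peak, limma called 97 of 4737 peaks higher in ChIP than in input and 0 lower, with 614 peaks at an unadjusted p under 0.05. limma-voom also called 0 lower. Of the 97 called peaks, 74 lay on Uextra, 20 on arms 2L to X, 2 on U and 1 on a heterochromatin sequence. With distinct reads limma called 179 peaks, of which 83 were on Uextra and 73 on arms, and 59 peaks were called both ways, 5 of them on arms. The input held at least 1.5 reads per position at 89 of the 125 Uextra peaks, against 10 of 4336 on the main arms. Distinct folds may be inflated at such peaks. The binomial test passed 1389 peaks in both libraries with all reads and 463 with distinct reads. Independent lists of the observed sizes (2248 and 3017 peaks with all reads, 1057 and 2092 with distinct reads) would share 1432 and 467. Unchanged libraries simulated against 1 shared input (means of 20 draws) gave far shorter lists, so their shared counts are not comparable with these. With all reads they passed 260 and 220 peaks and shared 18.1 (12.1 if independent) when the input varied by counting error alone, and passed 788 and 803 and shared 354 (134 if independent) when it varied like the ChIP libraries. With distinct reads they passed at most 9.1 peaks on average.

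The 20 peaks with the highest lower fold were all called with all reads, and 19 lay on Uextra and 1 on U. With distinct reads 14 of them were called by limma and 6 were not. At Uextra 24444488 to 24444883 the log2 folds were 7.11 and 6.01 (limma estimate 6.56, SE 0.70, adjusted p = 2.25e-17), but with 12, 10 and 8 distinct reads in replicate 1, replicate 2 and the input it was not called (limma estimate 3.99, SE 1.79, adjusted p = 0.173). At Uextra 28555377 to 28556062, called both ways, the log2 folds were 6.73 and 5.97 (limma estimate 6.35, SE 0.67, adjusted p = 1.81e-17). On U, the peak at 2768989 to 2769405 had folds of 5.57 and 4.33. The reads of such peaks were stacked on very short segments. Over the Uextra peaks the strand offset had a median of 34 bp (quartiles 31 to 36.5), near the read length of 35, against 208 bp on the main arms and fragment lengths of 324 and 358 bp. In the median Uextra peak 93.3% of distinct ChIP ends and 93.8% of distinct input ends fell within 100 bp, while in the median arm peak the densest 100 bp held 31.6% and 28.6%.

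**Figure D2:**
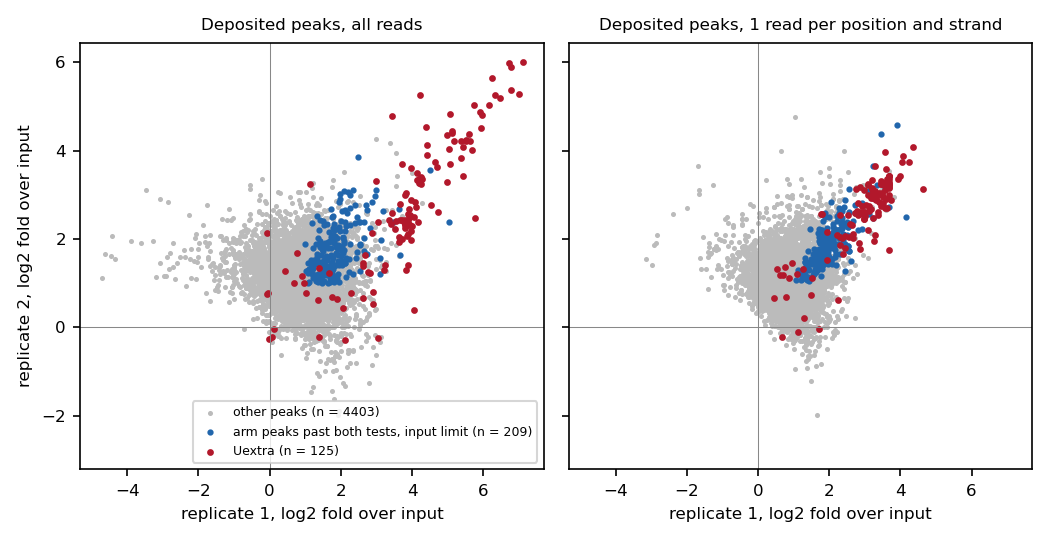
Log2 fold over input of each deposited peak in replicate 1 (horizontal axis) and replicate 2 (vertical axis), with all reads on the left and 1 read per position and strand on the right; points are peaks, red on Uextra (125), blue for the 209 arm peaks that passed the binomial test in both libraries with both kinds of read counting where the input held under 1.5 reads per position, grey for the others. Uextra medians are 3.89 and 2.47 with all reads and 3.20 and 2.77 with distinct reads.

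On the arms the highest-ranking peak was 3L 13284929 to 13285708, with log2 folds of 4.50 and 3.57 (limma estimate 4.03, SE 0.80, adjusted p = 3.65e-05) and of 3.90 and 4.59 with distinct reads. It was not called with limma-voom. Its ends were also stacked: 13 of 13 minus-strand ends of replicate 1 lay between 13285305 and 13285336, 7 of 9 plus-strand ends lay between 13285273 and 13285302, and the strand offset was 27 bp. The input was partly stacked there too, with 7 of its 14 minus-strand ends between 13285305 and 13285333. Among the other arm peaks called by limma were X 8099509 to 8100060 (estimate 3.76, SE 0.79), X 14076610 to 14077133 (3.38, SE 0.77), 2L 19260323 to 19260858 (3.63, SE 0.80) and 2L 11814556 to 11815075 (2.97, SE 0.87). These 4 rested on 3 to 11 distinct reads per ChIP library and were not called with distinct reads. Other arm peaks, outside the named regions, were called both ways. At 2L 626209 to 627238 the log2 folds were 5.05 and 2.39 (limma estimate 3.72, SE 0.68, adjusted p = 4.87e-06, and 0.012 with distinct reads), with a strand offset of 246 bp. Also called both ways were 3R 13725993 to 13726801 (strand offset 260 bp) and 3L 16306081 to 16307077 (333.5 bp). The leading peaks of 2R, 3R and 4 were not called: 2R 4357380 to 4357895 had folds of 2.65 and 2.38, 3R 16686049 to 16686549 had 2.96 and 2.97, and 4 609680 to 610184 had 1.61 and 1.60.

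**Figure D3:**
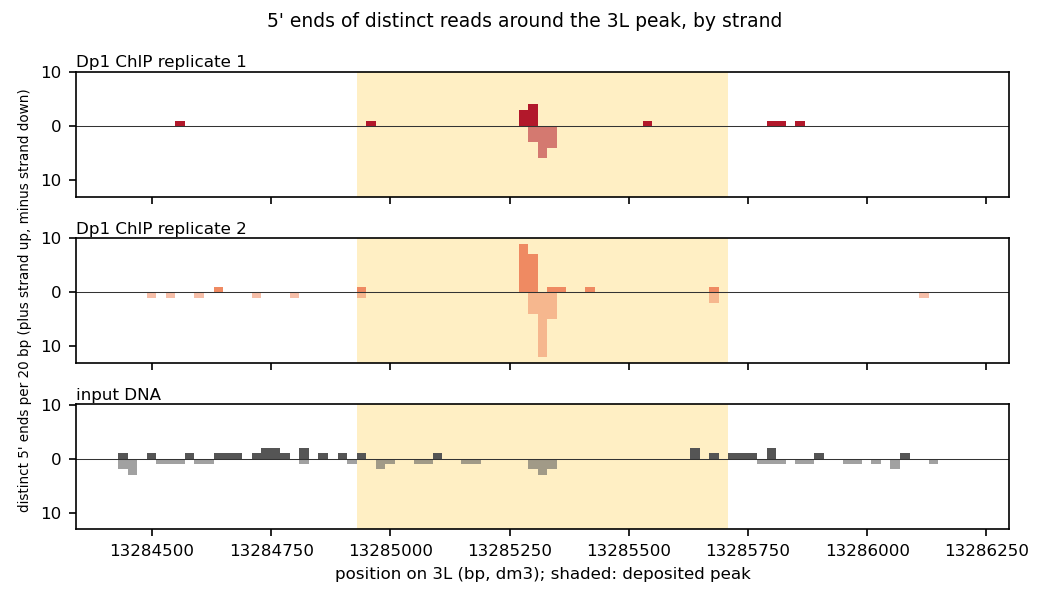
Distinct 5' ends per 20 bp (vertical axis, plus strand up and minus strand down) around 3L 13284929 to 13285708 (horizontal axis, bp, dm3; shaded), 1 panel per library. In both ChIP libraries the ends of both strands are piled within the same short segment, with a strand offset of 27 bp; the input has 7 minus-strand ends there and no plus-strand ends.

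A set of 209 arm peaks, 4.82% of those on the main arms, passed the binomial test in both libraries with all reads and with distinct reads where the input held under 1.5 reads per position; without this limit 212 passed. This set was drawn after the values were seen and includes the 3L peak. It held 69 peaks on 3R, 41 on 3L, 39 on 2R, 29 on 2L, 28 on X and 3 on 4. High folds in both replicates follow from this choice, which used the same reads. Over all deposited peaks, passing in both libraries was about as frequent as for independent lists. The counts were 1389 against 1432 with all reads and 463 against 467 with distinct reads. Membership therefore does not show that the replicates agree. Nor does it show that they disagree: if these ChIP libraries entered the peak call, overlap within the list depends on that choice. The set's median strand offset was 214.5 bp, and 164 of 208 peaks with a value had at least 100 bp, a share close to that of all arm peaks (median 208 bp, 3419 of 4228). For the arm peaks that limma called with all reads the median was 135 bp, and 11 of 19 had at least 100 bp. limma called 48 of the 209 with distinct reads and 5 with all reads. Among the former were 3R 3355773 to 3356449, with distinct log2 folds of 3.24 and 3.65 (limma adjusted p = 1.06e-05, strand offset 218 bp), and 2R 20152477 to 20153261, with 2.44 and 2.88 (limma adjusted p = 0.000233, strand offset 370.5 bp). 2R 6381583 to 6382148 had distinct folds of 3.69 and 2.72 (limma adjusted p = 0.0323) and 3R 27887416 to 27887986 had 3.36 and 3.22 (limma adjusted p = 0.0438). With all reads none of these peaks was called (limma adjusted p = 0.363, 0.403, 0.423 and 0.582 in the order given). Their all-read log2 folds ran from 1.65 to 3.66. By contrast, 2R 2235049 to 2235408 had distinct folds of 3.52 and 3.28 but all-read folds of 0.32 and 0.24, with 3363 input reads at 72 positions.

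The second comparison asked how far the replicates resembled each other. A log2 fold of at least 1 was reached in both replicates at 1436 peaks, in replicate 1 alone at 861, in replicate 2 alone at 1581 and in neither at 859. Across peaks, which are not independent replicates, the folds of the replicates correlated with Pearson r = 0.128 and Spearman rho = -0.034 when each was set against a separate part of the input, and over the peaks of the main arms r was -0.117 and rho -0.104. With distinct reads r was 0.179 and rho 0.068 over all peaks, and r was 0.0078 and rho -0.0093 over those of the main arms. If these ChIP libraries entered the peak call, the choice of peaks can itself lower correlations across peaks. The values over peaks then do not measure how far the replicates agree. Over 1-kb bins of the arms r was 0.0857 and rho 0.101 with all reads, and 0.185 and 0.208 with distinct reads. With the whole input shared, r was 0.180 over peaks (covariance 0.139) and 0.112 over bins (covariance 0.141). Unchanged libraries simulated against 1 shared input gave an r of 0.0346 and 0.0289 (covariance 0.0223 and 0.0285) when the input varied by counting error alone, and of 0.475 and 0.476 (covariance 0.566 and 0.872) when it varied like the ChIP libraries. Over bins the observed covariance of 0.141 lay below all draws of the latter (0.862 to 0.881). With all reads this argues against an input that varied as much as the ChIP libraries, which the limma fits assume. Their standard errors over bins with all reads may therefore be too large. With distinct reads and the whole input shared, r was 0.277 over peaks and 0.240 over bins (covariance 0.142 and 0.161), against 0.0550 and 0.0585 (covariance 0.0299 and 0.0297) and 0.194 and 0.201 (covariance 0.122 and 0.121) in the same simulations. Read numbers in arm peaks differed between replicates with a chi-square per degree of freedom of 12.2 with all reads, 1.62 with distinct reads and 1.06 with distinct plus-strand reads.

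The third comparison extended the count to 1-kb bins. Over all sequences limma called 79 of 122415 bins higher, of which 71 lay on Uextra and 60 overlapped a peak. The 79 included 1 bin on 2L and 1 on X, both within a peak. When the 114217 bins of the 6 main arms were fitted alone limma called 0, with 481 at an unadjusted p under 0.05, and limma-voom also called 0. On simulated counts the limma fit recovered only 2% of 8-fold and 12% of 16-fold changes in such bins. The 0 calls therefore do not show that the arms lacked enriched bins. The binomial test passed 1793 bins in both libraries, and 614 of these overlapped a peak, as did 7339 of all tested bins. Independent lists of the observed 9255 and 10677 bins would share 865. The simulated unchanged libraries passed 8647 and 8288 bins and shared 739 (627 if independent) with counting error alone in the input. They passed 22118.5 and 24097.5 and shared 10706 (4667 if independent) when it varied like the ChIP libraries. The latter lists were far longer than the observed ones, so their shared count is not comparable with 1793. With distinct reads the test passed 213 and 1897 of 113419 bins and 49 in both, where independent lists would share 3.56. The simulations passed 3.1 and 10.4 bins and shared 0, or passed 152 and 280 and shared 6.5 (0.375 if independent). These lists were shorter than the observed ones, so their shared counts are not comparable with 49. Of the 49, 37 overlapped a peak, as did 7332 of all tested bins, and 7 had at least 1.5 input reads per position, which leaves 42 with 30 in a peak. Among 100889 bins, those chosen as the top 1% in replicate 1 had a pooled log2 fold in replicate 2 that was 0.45 above the other bins (95% bootstrap interval 0.39 to 0.50). Those chosen in replicate 2 were 0.32 above the other bins in replicate 1 (0.25 to 0.38). Each interval rests on 1 library for the choice and 1 for the measure, so it covers no spread between libraries.

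The fourth comparison set the number of peaks on each sequence against its share of the input reads. X held 322 peaks where 562 were expected (ratio 0.573, exact binomial test, adjusted p = 9.92e-30), and 3R held 1333 where 1224 were expected (1.09, adjusted p = 0.00084). The test takes each peak of the deposited list as an independent draw. Its p-values therefore measure neither the spread between libraries nor that between regions. More peaks than expected also lay on Uextra (ratio 1.94), U (1.5), 2LHet (2.59), 2RHet (1.63), 3LHet (1.48), 3RHet (1.77) and the mitochondrial genome (9 peaks, 7.72). Counts on 2L (ratio 1.01), 2R (0.948), 3L (1.01) and 4 (0.655) did not depart from expectation at an adjusted p under 0.05, and neither XHet nor YHet, with 1.98 and 0.0502 peaks expected, held a peak. With arm length as the expectation, the excess on 2RHet, 3LHet, U and Uextra turned into a deficit, and 2LHet (ratio 1.64) and 3RHet (1.06) no longer departed. More peaks than expected by length lay on 2L (1.22), 2R (1.59), 3L (1.36), 3R (1.70) and the mitochondrial genome (25.8), and fewer on X (0.511), 4 (0.377), XHet and YHet. Mitochondrial reads carry different sequence names in the ChIP and input files, and whether the peak call joined them is not given. The mitochondrial excess by either expectation may follow from that. For the higher-scoring peaks alone, against input reads, the excess on 3R was not called.

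**Figure D4:**
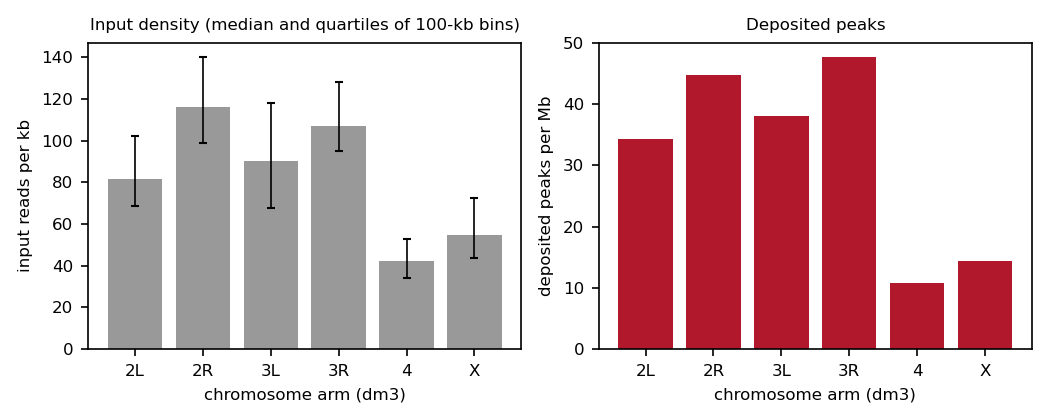
Input reads per kb (left; bars are medians of 100-kb bins and whiskers their quartiles) and deposited peaks per Mb (right) on each of the 6 main arms in dm3. X has a median of 54.8 reads per kb and 14.4 peaks per Mb, and 3R 107 reads per kb and 47.7 peaks per Mb.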

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

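The test of Uextra against a thinned input was chosen after the Uextra excess was seen, and the limit above which it counts against copies was lowered from 2 to 1.5 after its ratios were seen. Uextra lies outside the arms on which the background was set, and it took 12.6% of the reads of Dp1 ChIP replicate 1 and 5.49% of replicate 2, against 1.36% of the input. A larger share of the same sequences throughout would have raised most of Uextra, yet 29.2% of 569 bins of 1 kb reached a log2 fold of 1 in both replicates, which argues against it. Amplified copies placed without error were taken to add no distinct positions (a ratio of 1). The distinct positions were 1.66 (95% counting interval 1.61 to 1.72) and 1.64 (1.59 to 1.69) times those of an input thinned to equal background. Both ratios lie above the limit of 1.5 and below the earlier limit of 2, and the intervals cover counting error only. The test therefore cannot decide whether copies were the whole cause. Copies stay open as a part or the whole of it, with 42.8 and 46.2 reads per distinct position. Misplacement of copies with read errors was not tested and also stays open. Stacking on short segments was similar in ChIP and input (medians of 93.3% and 93.8% of ends within 100 bp), and the mitochondrial genome gave 1.86 and 3.06 by the measure with the thinned input. No biological explanation was tested, since the sequence of these segments was not analysed here; whether they hold satellite DNA bound by a Dp1 protein stays open.

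Exact read positions were shared between the ChIP replicates on the arms 2.69 times as often as positions offset by a fixed distance, at 12788 positions or 1.51% of those of replicate 1, against 1.32 and 1.23 times between each ChIP replicate and the input.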

How the results depend on the processing

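Alternatives chosen after seeing the data were plus-strand counts, binomial tests on distinct reads, the 209-peak set and main arms alone. The median log2 fold of the peaks stayed positive in every setting run (0.86 to 1.23) and was 0.97 to 1.23 with 1 replicate left out. The 97 called peaks became 179 with distinct reads, 173 on the plus strand alone, 423 with limma-voom, 1389 and 463 with the binomial test on all and distinct reads, 209 on the main arms with both and under 1.5 input reads per position, and 20 on the main arms alone; other settings gave 78 to 104. The 79 called bins of all sequences became 141 without a filter, 157 with a pseudocount of 5, 164 after thinning, and 2428 and 212 with the binomial tests. The 0 arm bins called by limma when fitted alone (481 at an unadjusted p under 0.05) became 3 with scaling by all reads, 7 with distinct reads, 2 without a filter, 4 with a pseudocount of 5, 5 after thinning, and 1793 and 49 with the binomial tests; limma-voom and 500-bp bins gave 0. The share of reads in peaks was 6.18%, 6.62% and 3.33% (replicate 1, replicate 2, input) with distinct reads, 15.5%, 8.98% and 2.94% for the higher-scoring peaks, 17.9%, 11.6% and 4.33% without the shift, and 6.34%, 6.88% and 3.22% on the main arms. The replicates' Pearson r was 0.179, 0.185 and 0.180 over peaks and 0.185, 0.102 and 0.112 over bins with distinct reads, a pseudocount of 5 and the whole input shared; Spearman rho over peaks was 0.068, -0.033 and 0.017 there. On the main arms alone 2 sequences departed from expectation instead of 9, as fewer were tested. By length, ratios reversed to 0.673 on 2RHet, 0.753 on 3LHet, 0.209 on U and 0.153 on Uextra. Except where construction shows it, the cause was not tested. Of 42 named peaks, 10 lost and 2 gained their call with distinct reads, 14 lost and 4 gained it on the plus strand alone, and 7 lost and 1 gained it with limma-voom. Median distinct reads per peak of 9 and 12 limit single peaks. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Not run: bin tests without 1 replicate, promoter windows and their limma fits by window size, GC correction, and every alternative on gene positions, gene lists and motifs.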

Other observations

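The test on bins chosen in 1 replicate was picked after the agreement of the replicates had been seen. The test over all of X was set before its value was seen, but its interval was picked after others had been tried, and the test on X bins of central density was added last, after all of these values had been seen. Input density differed between the arms; DNA copy number, mappability and GC content were not separated. Its median was 116 reads per kb on 2R, 107 on 3R, 90.3 on 3L, 81.9 on 2L, 54.8 on X and 42.1 on 4. Relative to the autosomal median these are 1.15, 1.06, 0.895, 0.811, 0.543 and 0.418. YHet held 130 of 12265674 input reads, at 0.376 reads per kb, against 25.4 on XHet and 46.2 on 2LHet.

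X held 14.4 peaks per Mb against 41.4 on arms 2L, 2R, 3L and 3R, a ratio of 2.88, and a lower input density that leaves fewer reads to call peaks from is a candidate explanation. For the 112 X bins of 100 kb at 43.5 to 72.6 reads per kb, which hold 78 of the 322 peaks of X in such bins, autosomal bins of the same density gave an expected 217 peaks, or 2.78 times as many (bootstrap over 1-Mb blocks, 1.998 to 4.22), which argues against it there. Over all of X a lower input density cannot be told apart from other causes. The test there set unlike bins side by side: autosomal bins in that range, at 23.3 peaks per Mb, and all 224 X bins, at 14.4. Their ratio was 1.62, with an interval of 1.11 to 2.44 over 1-Mb blocks and of 1.28 to 2.04 over single bins, on both sides of the limit of 1.5. The X bins in that range held 6.96 peaks per Mb. In the set of 209 arm peaks past the binomial tests at under 1.5 input reads per position, X had 28 (8.70% of its peaks, against 4.82% over all arms), and chromosome 4, also of low input density with 10.8 peaks per Mb, had 3 of its 14 (21.4%). GC content, mappability and the peak caller's settings stay open as untested, and no biological explanation was tested.

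Bins that rank high in 1 replicate were also higher in the other, and chance choice of the bins by counting error as the whole cause would have left no difference. The median log2 fold in the replicate not used for the choice exceeded that of the other bins by 0.37 and 0.23, which argues against it. The excess is well below the median of 0.97 and 1.23 at the deposited peaks, which may have been chosen on these same reads. Biases that both ChIP libraries share against the input, such as their longer fragments (324 and 358 against 234 bp), stay open and were not tested, and so does Dp1 binding. Variation of the single input beyond counting error, which both of its parts share, also stays open, since 1 library does not give its size: set to that of the ChIP libraries in simulations, it gave a distinct-read r over bins of 0.201 with the input shared, against 0.240 in the data.

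The deposited score followed the measured fold weakly on the arms, with a Spearman rho across 4336 peaks of 0.133 with all reads and 0.129 with distinct reads. Opposite-strand ends 260 to 430 bp apart exceeded the level at 100 to 200 bp by 36.1 pairs per 100 plus-strand positions outside peaks in replicate 1 and by 48.8 in replicate 2, and by 42.1 and 61.0 in or near peaks. As a ratio to that level, pairs at the fragment length went the other way. They stood at 1.60 and 1.73 outside peaks and at 1.55 and 1.67 in or near them. In the input, with its shorter fragments of 234 bp, the excess was -10.7 outside peaks and -9.01 in or near them.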
